A study of Mus musculus with 7 samples.

How the data were processed

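RNA was measured by sequencing in 7 samples of the mouse line 3T3-L1. Per the labels' protocols, total RNA was column-purified, depleted of ribosomal RNA and made into directional libraries. The submitters' processing notes name kallisto 0.46.1, a pseudoalignment quantifier, and the build mm10. The file name describes the deposited values as TPM, an abundance scaled by transcript length and library total. How transcripts were combined into gene symbols and how rows were selected is not given in the sources used here.

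All 7 value columns of the deposited table carried generic names, and 0 of these names occurred in any sample title, description, source name or characteristic. The 7 columns were left out of every result. Their ranges, sums, some rows and correlations were viewed while the file was inspected, and none of this was used to assign a column or to compute a result. The group fits, gene list tests and alternatives that had been set before the data were examined were not run, for the same reason. The sample titles and the cell line field disagree, since the field counts upward from 3T3-L1 over the samples while every title says 3T3-L1, and the titles were used.

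The gene column alone was analysed, with Python 3.11.15 and pandas 2.3.3. Names were matched exactly to gene symbols of GENCODE M21, which is built on GRCm38, the assembly that mm10 denotes. A second matching also accepted older symbols and RefSeq synonyms. The 30 gene lists were fixed before the data were examined. These counts are of names, so they have no replicate error, and no test was made.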

Results

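The series profiled RNA from 3T3-L1 cells, a mouse fibroblast line that can be differentiated into adipocytes in culture. Differentiated cells were assigned by the sample titles to 3 groups. PBS-treated cells gave 2 samples. Cells exposed to recombinant TGF-β1, a cytokine that regulates extracellular matrix production, for 4 days gave 2 samples. Cells titled as TGF-β1-free for 14 days gave 3 samples. The titles of these samples do not mention an earlier exposure. Their treatment field names TGF-β1 followed by TGF-β1-free, and the series' design text states that the exposure lasted 4 days and that the 14 days were spent in TGF-β1-free medium afterwards. The titles do not say how long the PBS-treated cells were cultured. The groups bear on which transcripts differ after exposure to TGF-β1 and on which differences from PBS are seen after its removal. The TGF-β1-free cells also spent 14 further days in culture. A difference between them and the cells exposed for 4 days could not separate removal from time in culture. The samples hold no separate PBS group for the 14 further days. A difference between the TGF-β1-free cells and PBS-treated cells could therefore also not be separated from time in culture by the titles.

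No expression value is given here for any group, and no comparison between groups was made. The table held 7 value columns whose names appeared in no sample label, so no column was assigned to a sample. The order of the columns and the values in them were not used in place of a label. Fold changes, their errors and tests for TGF-β1 against PBS, for TGF-β1-free medium against PBS and for TGF-β1-free medium against TGF-β1 were therefore not analysed here. Depth per sample was likewise not analysed.

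The genes that the table lists could be described without its values. It held 12309 rows, of which 1 carried no gene name, and the other 12308 names were distinct. By current symbol, 11788 of them matched the GENCODE M21 annotation. Of these matches, 11451 were protein-coding genes, 325 were pseudogenes and 12 were long non-coding RNA genes. The presence of a gene in the table gives no level of expression, and the rule by which the rows were selected is not given in the sources used here. A missing gene, or a small count for a class of genes, therefore does not show absence from the cells.

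Fbn1 was among the listed genes. It encodes profibrillin-1, whose C-terminal cleavage product is asprosin, the hormone named in the series title. In GENCODE M21 (GRCm38/mm10), Fbn1 (ENSMUSG00000027204.13) lies on the minus strand of chromosome 2 from 125300594 to 125507993. Its longest annotated coding transcript has 65 exons and 11971 exonic bases. The table gives 1 row per gene symbol, so the coding transcripts of Fbn1, of which the annotation holds 2, are not separated in it.

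Of 736 distinct gene symbols in 30 lists drawn up for adipocytes and TGF-β1 treatment, 613 were listed. Some lists hold a gene under both its older and its current symbol, so the counts are of symbols. With older symbols and synonyms accepted, the TGF-β target list rose to 32 of 33 and insulin signalling and glucose uptake to 24 of 24. Nuclear-encoded oxidative phosphorylation rose to 40 of 40. The added symbols were found through another name, and whether each such name belonged to a single gene was not checked. All 23 genes of the collagen list and 28 of 29 of the myofibroblast and contractile list were listed. The fibrillin and elastic microfibril list had 25 of 28 genes, and the TGF-β target list had 29 of 33. The list of profibrillin cleavage enzymes and asprosin receptors had 4 of 10. With the lists of other cell types left aside, this was the lowest share, close to the 8 of 18 of the thermogenic list. A gene held under both symbols could change that order. Among adipocyte lists, 23 of 26 transcription factors, 23 of 28 genes of fatty acid and triglyceride synthesis, 19 of 25 genes of lipolysis and the lipid droplet and 16 of 21 adipokines were listed. The thermogenic list had 8 of 18 genes. Insulin signalling and glucose uptake had 21 of 24, preadipocyte and mesenchymal progenitor markers 21 of 27, and inflammatory cytokines and chemokines 26 of 34. Matrix proteases, their inhibitors and collagen processing had 31 of 34, β-oxidation and the TCA cycle 30 of 31, nuclear-encoded oxidative phosphorylation 37 of 40 and cholesterol synthesis 23 of 24. The interferon response had 32 of 33, glycolysis and the hypoxia response 27 of 28, and DNA and histone modifying enzymes 39 of 40. The lists of 33 cell cycle genes, 24 genes of the unfolded protein response and 39 ribosomal protein genes were found in full. These lists were not checked to be complete gene families. Of the mitochondrially encoded genes 12 of 13 were listed, and of the immediate early and heat shock genes 19 of 22. Markers of other cell types were listed for 3 of 16 leukocyte genes, 5 of 12 endothelial genes, 2 of 14 skeletal muscle genes, 8 of 19 osteoblast and chondrocyte genes and 3 of 11 epithelial genes. These counts describe only which names the gene column holds and carry no direction of change.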

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

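Both matchings were chosen after the data were seen. Accepting older symbols and synonyms raised the matched names from 11788 to 12244 and left 64 names unmatched. The same change raised the list symbols found from 613 to 628. It took TGF-β targets from 29 to 32 of 33, insulin signalling and glucose uptake from 21 to 24 of 24, and nuclear-encoded oxidative phosphorylation from 37 to 40 of 40. Adipocyte transcription factors went from 23 to 25 of 26, fatty acid and triglyceride synthesis from 23 to 25 of 28, matrix proteases and collagen processing from 31 to 32 of 34, and leukocyte markers from 3 to 4 of 16. For these lists, that part of the shortfall by the lists' own symbols was met through an older symbol or synonym. A gene that a list holds under both its older and its current symbol can be counted at each. Whether each synonym belonged to a single gene was not checked. The counts of the remaining lists, profibrillin cleavage and asprosin receptors at 4 of 10 among them, did not move. No paired analysis was possible because the value columns carried no sample or replicate names. For that reason the settings chosen before the data were examined (pseudocount, filter, scaling, spread model, samples in the fit, replicates left out and the list tests) were not run.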
